A study of Drosophila melanogaster with 4 samples.

How the data were processed

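ZW5 ChIP-seq was carried out on crosslinked chromatin of Oregon-R embryos 14 to 16 h old, per the labels' protocols. The labels give 2 ChIP and 2 input libraries, and each input library served as input for the region list of the ChIP library with the same number. The authors deposited a list of enriched regions for each ChIP replicate and a list for the series as a whole, called the combined list here. Coordinates are on FlyBase release 5, per the file headers. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The caller, its threshold, its filters and the way the replicates were combined are not given in the sources used here. The input libraries had no list of their own and entered only through the authors' calls.

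The value of each region is a score the authors deposited, and the file headers do not state its scale. Scores shared by at least 3 regions were compared with each other. Read as log2 values, 72 of the 105 pairs of such scores from 1.5 upwards in the combined list were ratios of whole numbers up to 40 within a relative tolerance of 1e-06. Read as natural logarithms 0 of the 105 were, as log10 values 2, and as linear values 0. Over all scores, 5 of 6 such pairs in replicate 1 and 41 of 325 in replicate 2 (12.6%) were simple ratios as log2 values, against 0 and 2 as linear values and 0 under the other readings. The log2 reading thus gave the most simple ratios in each list, but it left most pairs of replicate 2 without one, and the scale is not stated. Scores were used to describe, rank and filter regions within a list. Between lists they were compared as ranks, as deposited values for Pearson's r, and by the same boundary of 1 in each list. Scores were called tied when they were equal to 9 decimals. Every deposited region was used, and no filter on scaffold or score was applied in the main results. The combined list was treated as pooled and given no replicate error.

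Regions were called shared when they overlapped by at least 1 bp. Chance overlap came from 10000 random placements within the chromosome lengths in the file headers, with widths kept and overlap among placed regions allowed. Correlations between scores paired each replicate 1 region with its largest overlap in replicate 2 and used 100000 permutations, as did differences between medians. Arm counts were compared with 100000 multinomial draws in proportion to arm length. As planned for the case of no reference of the same build, arm length was the span from the first to the last combined-list region, which covered 98.3% to 99.7% of the header length on the 5 large arms. Shares carry 95% Wilson intervals, densities 95% exact Poisson intervals, and a share of 0 the limit set by 3 counts. Exact binomial and Fisher's exact tests were 2-sided, and their adjusted p-values are Benjamini-Hochberg values within the family named. The permutation tests of overlap, of arm counts and of close neighbours were 1-sided towards larger values, and the others 2-sided. Seeds were fixed at 1.

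The named regions were chosen by a rule fixed before the data were examined. It took the combined-list regions with the highest score that both replicates overlapped, with nearest genes for 20 of them if an annotation of the same build was given and otherwise the positions of the first 10 only. The gene table at hand is for release 6 and was not used, since coordinates were not converted between builds. The planned results on promoters, divergent promoters, gene lists and motifs, and the fixed genes, were therefore not analysed here. Read depth is unknown, so no precision from depth is given.

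Alternatives covered the overlap rule, list length, placement scheme, scaffolds, stricter score limits and each replicate left out; others were added after the data were seen, namely the division at a score of 1 and at 0.8 and 1.5, draws from the weak regions of the combined list, header lengths, arm counts without X and chromosome 4, placement without overlap, the tests of width and of support by a single replicate, the limit to combined-list regions at least as wide as the narrowest replicate region, and the tests of X. The functions were tested on simulated data. In 100 simulated list pairs with 628 replicate 1 regions at random positions, the overlap test gave p under 0.05 in 3, and with 60 planted shared regions in 100. The spacing test gave 1 of 100 for random and 100 of 100 for grouped regions. With 275 simulated regions on the 5 large arms, the arm test gave 5 of 100 for an even spread and 100 of 100 for a sparse X. The planted X was sparser than that of the 275 regions overlapped by both replicates, at 0.506 times the autosomal density. Power at that density was not measured. The rank correlation over 100 simulated pairs gave 4 of 100 without and 100 of 100 with a planted relation. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.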

Results

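Binding of ZW5 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster embryos collected 14 to 16 h after egg laying. ZW5 (zeste-white 5) is a zinc-finger protein known to bind the scs boundary element at a heat shock locus, and Oregon-R is a wild-type laboratory strain. The labels describe 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group. A list of enriched regions was analysed for each ChIP replicate, together with 1 list for the replicates combined. No read counts were analysed here, so the depth of each library is unknown. Intervals on shares and densities cover counting error only. The labels do not say that the replicates came from separate embryo collections, and the p-values are across regions, which are not independent replicates.

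Replicate 1 held 673 enriched regions, replicate 2 held 1057 and the combined list held 5135. The regions had a median width of 1597 bp in replicate 1, 1560 bp in replicate 2 and 1251 bp in the combined list. They covered 1.32 Mb, 1.98 Mb and 7.32 Mb, or 0.781%, 1.18% and 4.34% of the sequence named in the file headers. Most regions lay on the large chromosome arms 2L, 2R, 3L, 3R and X: 628 of replicate 1, 1042 of replicate 2 and 4837 of the combined list. The unplaced scaffolds collected as U held 36, 9 and 162 regions, and the heterochromatic scaffolds held 7, 5 and 123. The score, a value the authors gave each region, had a large mode under 1 in each list and a long tail above it. A score of at least 1 was reached by 195 regions of replicate 1 (29.0%), 184 of replicate 2 (17.4%) and 336 of the combined list (6.54%). This boundary was chosen after the scores were seen, and regions above and below it are called strong and weak here.

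The strongest binding lay on 2L, 2R, 3L, 3R and X and stood at the top of all 3 lists. The first of the 10 named regions lay on 3R at 19782710 to 19785874, with a combined score of 4.93 and rank 1 in each replicate. The next were X 15216202 to 15218784 with a score of 4.57, 3R 17847222 to 17850496 with 4.52, 2R 17556104 to 17559490 with 4.46 and 3R 16645870 to 16649764 with 4.45. They were followed by 2R 12082370 to 12086328 with 4.38, 2L 1971932 to 1975438 with 4.32 and 3L 2779330 to 2783956 with 4.30. X 19372364 to 19375840 scored 4.28, and 3L 5143792 to 5147070 scored 4.23. Each of the 10 was among the 14 highest scores of replicate 1 and the 12 highest of replicate 2, and their widths ran from 2583 to 4627 bp. Coordinates are those of FlyBase release 5, the build in the file headers. The gene or element at each position is not given, because an annotation of this build was not used here.

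The replicates shared most of their strong regions and few of their weak ones. Over all scaffolds, 161 of 195 strong regions of replicate 1 (82.6%, 95% Wilson interval 76.6 to 87.2) were overlapped by replicate 2, and 175 of 184 of replicate 2 (95.1%, interval 91.0 to 97.4) by replicate 1. On the 5 large arms, 161 of 167 strong regions of replicate 1 (96.4%, interval 92.4 to 98.3) and 175 of 177 of replicate 2 (98.9%, interval 96.0 to 99.7) were shared. On X, 10 of 13 strong regions of replicate 1 (76.9%) were shared against 151 of 154 (98.1%) on the autosomal arms (adjusted Fisher's exact p = 0.0076 over 7 tests chosen after the data were seen), and in replicate 2 13 of 13 against 162 of 164 (adjusted Fisher's exact p = 1). Of all regions on X, strong and weak, 25.5% of replicate 1 were shared against 49.2% on the autosomal arms (adjusted Fisher's exact p = 4.1e-05), and 17.2% of replicate 2 against 28.2% (adjusted Fisher's exact p = 0.00456). Fewer regions were strong on X, 12.3% against 29.5% in replicate 1 and 8.28% against 18.5% in replicate 2. The comparison of all regions therefore cannot separate location from strength. Of all weak regions, 123 of 478 in replicate 1 (25.7%, interval 22.0 to 29.8) and 102 of 873 in replicate 2 (11.7%, interval 9.72 to 14.0) were shared. On U, none of the 36 regions of replicate 1 was found in replicate 2, which allows a shared share of up to 8.33%.

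Over the full lists, 284 of 673 regions of replicate 1 (42.2%, interval 38.5 to 46.0) overlapped a region of replicate 2 by at least 1 bp. In the other direction, 277 of 1057 regions of replicate 2 (26.2%, interval 23.6 to 28.9) overlapped replicate 1. Random placement of replicate 2's regions within their chromosomes gave 21.4 shared regions of replicate 1 on average, so the observed number was 13.3-fold higher (1-sided permutation p = 0.0001, the smallest that 10000 placements can give). Draws from the positions of the combined list gave 122.0 shared regions on average and lowered this excess to 2.33-fold (1-sided permutation p = 0.0001). Of those 5135 positions, 2814 belonged to regions narrower than any replicate region, so the draws may set chance too low. The share by rank fell steeply after the 150 highest scores on the large arms. At ranks 151 to 200 it was 58.0% (interval 44.2 to 70.6) in replicate 1 and 70.0% (interval 56.2 to 80.9) in replicate 2. In replicate 1 it reached 16.0% (interval 8.34 to 28.5) at ranks 301 to 350 and was higher again at ranks 551 to 600, at 38.0% (interval 25.9 to 51.8). Regions past rank 600 in replicate 1 and past rank 1000 in replicate 2 did not fill a bin and were left out. The share at the lowest scores is therefore not given.

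**Figure D1:**
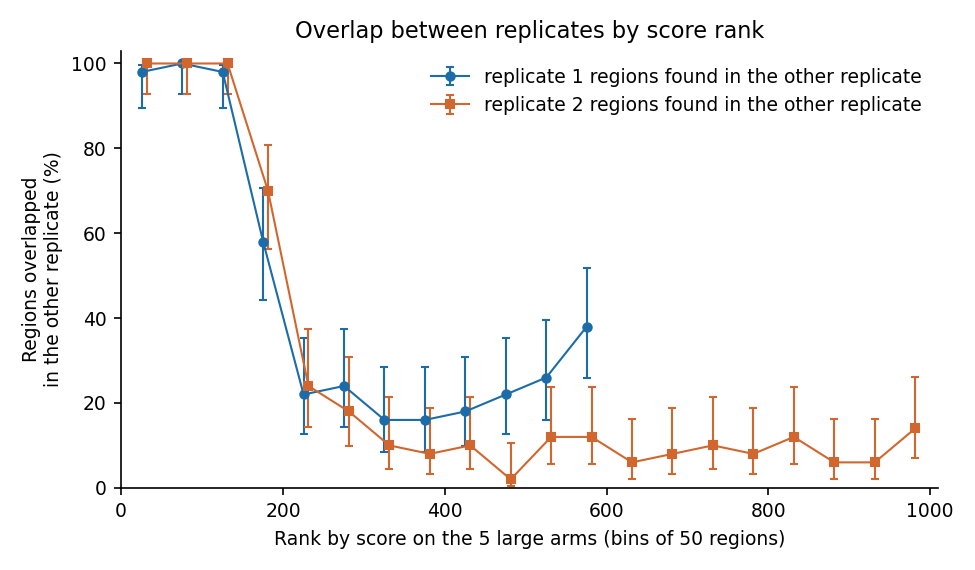
Percent of regions overlapped in the other replicate (vertical axis), for bins of 50 regions ranked by score on the 5 large arms (horizontal axis), with 95% Wilson intervals; circles are replicate 1 and squares replicate 2. The first 3 bins lie between 98% and 100% in both replicates, and the share falls to 22% and 24% at ranks 201 to 250. Replicate 1 stands at 38% in its last full bin. Regions past rank 600 in replicate 1 and past rank 1000 in replicate 2 did not fill a bin and are not drawn.

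Regions that scored high in replicate 1 also scored high in replicate 2. Over the 284 pairs of shared regions, Spearman's rho was 0.932 and Pearson's r was 0.967 (2-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Both members were strong in 161 pairs, both were weak in 102 and 1 of the 2 was strong in 21. Within the 161 strong pairs, spread over 2L, 2R, 3L, 3R and X, rho was 0.945. Within the 102 weak pairs it was 0.433 (2-sided permutation p = 1e-05 for the strong pairs and 2e-05 for the weak pairs). The 2 pairs farthest from the band, named after their values were seen, lay where 1 replicate 2 region spanned 2 replicate 1 regions. On 2L the replicate 2 score of 4.12 was paired with 0.38 at 8304888 to 8306626 and with 3.56 at 8306777 to 8309526. On 2R the score of 3.24 was paired with 0.44 at 17572177 to 17573478 and with 3.27 at 17573714 to 17576339.

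**Figure D2:**
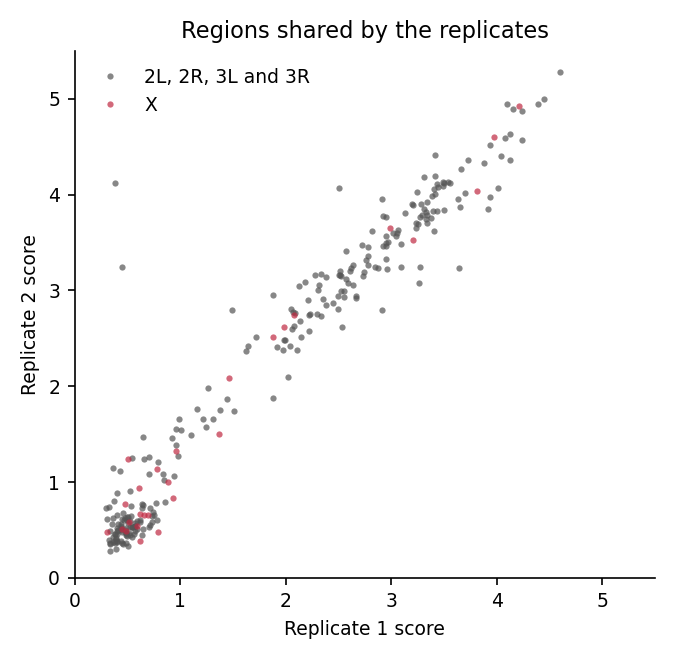
Score in replicate 1 (horizontal axis) against score in replicate 2 (vertical axis) for the 284 pairs of overlapping regions, with X in red and the other large arms in grey. A low group holds the 102 pairs under 1 in both lists, and the 161 pairs of at least 1 in both form a band up to 4.60 and 5.28.

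The combined list contained most regions of each replicate, strong and weak, and added many that neither replicate list held. It overlapped 172 of 195 strong regions of replicate 1 (88.2%, interval 82.9 to 92.0) and 181 of 184 strong regions of replicate 2 (98.4%, interval 95.3 to 99.4). Among weak regions, it overlapped 393 of 478 in replicate 1 (82.2%) and 722 of 873 in replicate 2 (82.7%). Of its 5135 regions, 275 (5.36%, interval 4.77 to 6.01) were overlapped by both replicates, 282 (5.49%) by replicate 1 only and 626 (12.2%) by replicate 2 only. The remaining 3952 (77.0%, interval 75.8 to 78.1) were overlapped by neither. The lists differ in their narrowest region, 1001 bp in the combined list and 1301 bp in each replicate, and 2605 of these 3952 were narrower than 1301 bp, so the share is not a measure of replication alone. The share with support was 23.0% from either replicate, 10.8% from replicate 1 and 17.5% from replicate 2. Among the 2321 combined-list regions of at least 1301 bp, a subset chosen after the data were seen, support from either replicate was 42.0% (interval 40.0 to 44.0).

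Regions supported by both replicates all lay on 2L, 2R, 3L, 3R and X, and they had higher scores than regions supported by neither. Their median score was 1.92, at percentile 96.2 of the combined list, against 0.39 and percentile 50.7 for regions supported by neither, a difference of 45.4 percentile points (2-sided permutation p = 1e-05). If the combined list pools the same libraries, regions called in both replicates would tend to score high in it. The score difference is then favoured by construction. Among regions of at least 1301 bp the difference was 66.2 points (2-sided permutation p = 1e-05). Their median width was 2773 bp, against 1169 bp for regions supported by neither, a difference that overlap with replicate regions of at least 1301 bp favours by construction. Regions supported by exactly 1 replicate had a lower median percentile than those supported by neither, 35.6 against 50.7 (2-sided permutation p = 1e-05), with 43.0 for replicate 1 only and 33.7 for replicate 2 only. Among regions of at least 1301 bp this difference was not found, at 31.2 against 30.0 (2-sided permutation p = 0.516). When the replicate 1 list was left out, the regions overlapped by replicate 2, those supported by both included, differed from all others by -1.90 percentile points (2-sided permutation p = 0.299). When the replicate 2 list was left out, the regions overlapped by replicate 1 differed from all others by 24.7 (2-sided permutation p = 1e-05).

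**Figure D3:**
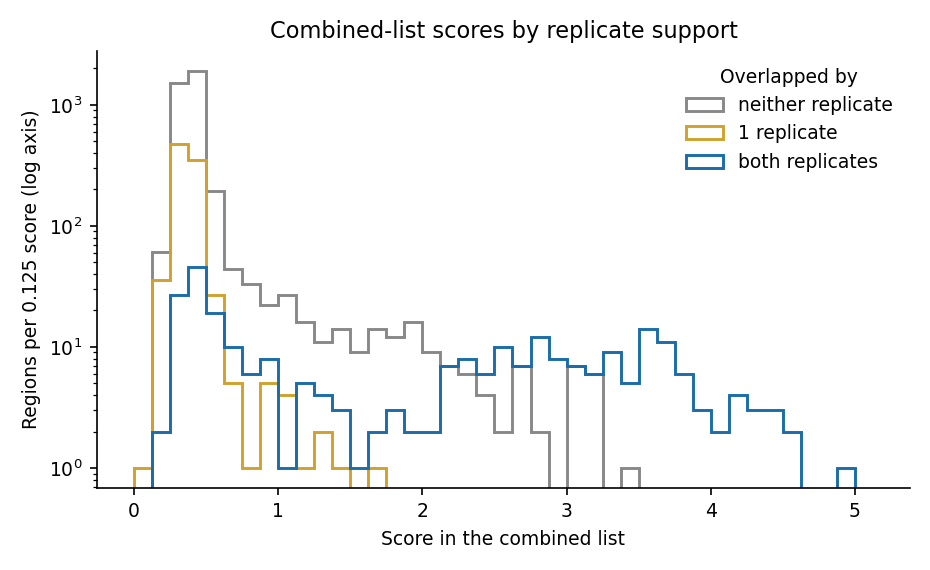
Number of combined-list regions per score interval (vertical log axis) against the score (horizontal axis), for regions overlapped by neither replicate, by 1 and by both. Regions overlapped by neither peak under a score of 0.5 and reach 3.38, and regions overlapped by both have a low mode and a broad high mode up to 4.93.

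Of the regions in the combined list, the small chromosome 4 held the fewest per Mb and 3R the most. Densities were 45.8 regions per Mb on 3R (95% exact Poisson interval 43.3 to 48.4), 43.7 on 2R (40.9 to 46.6), 39.6 on X (37.1 to 42.3), 38.5 on 3L (36.0 to 41.0) and 36.3 on 2L (33.8 to 38.8). Chromosome 4 held 13 regions, or 9.71 per Mb (5.17 to 16.6). The 3R density was 1.26 times that of 2L, and the counts departed from an even spread over these arms and chromosome 4 (chi-square 68.7, permutation p = 1e-05). The replicates' own lists departed as well (permutation p = 0.00474 for replicate 1 and 1e-05 for replicate 2). Among the 2567 regions of the combined list with the highest scores, the ratio of the highest to the lowest large arm rose to 2.17, with X at 30.4 regions per Mb and 2L at 14.0. Most of these 2567 were weak, since only 336 combined-list regions reached a score of 1. The median score of weak combined-list regions was higher on X, at 0.44 against 0.37 on the autosomal arms. The length of each arm was the span from its first to its last combined-list region.

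Among regions supported by both replicates, 2L held the most per Mb and X the fewest of the large arms. There were 70 on 2L (3.09 per Mb, exact Poisson interval 2.41 to 3.91), 78 on 3R (2.81 per Mb, 2.22 to 3.50), 51 on 2R (2.43 per Mb, 1.81 to 3.20), 47 on 3L (1.92 per Mb, 1.41 to 2.56) and 29 on X (1.30 per Mb, 0.869 to 1.86). X held 10.5% of these 275 regions (Wilson interval 7.44 to 14.7) and 18.9% of the summed span of the 5 large arms (exact binomial p = 0.0002, adjusted p = 0.00046 over 9 such tests). Of the 157 that were also strong, 10 (6.37%, interval 3.50 to 11.3) lay on X (exact binomial p = 1.4e-05, adjusted p = 9e-05). Of the 118 weak regions supported by both, 19 (16.1%, interval 10.6 to 23.8) lay on X, which did not pass the test (adjusted exact binomial p = 0.543), and neither did the full list of replicate 1, at 16.9% (adjusted exact binomial p = 0.304). The full list of replicate 2 had 15.1% on X (adjusted exact binomial p = 0.00241). Strong regions alone gave 7.78% on X in replicate 1 (adjusted exact binomial p = 0.00029) and 7.34% in replicate 2 (adjusted exact binomial p = 9e-05). Over 2L, 2R, 3L and 3R the 246 regions supported by both did not pass the test for an uneven spread (permutation p = 0.0666). The tests of X and of regions supported by both were chosen after the data were seen.

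**Figure D4:**
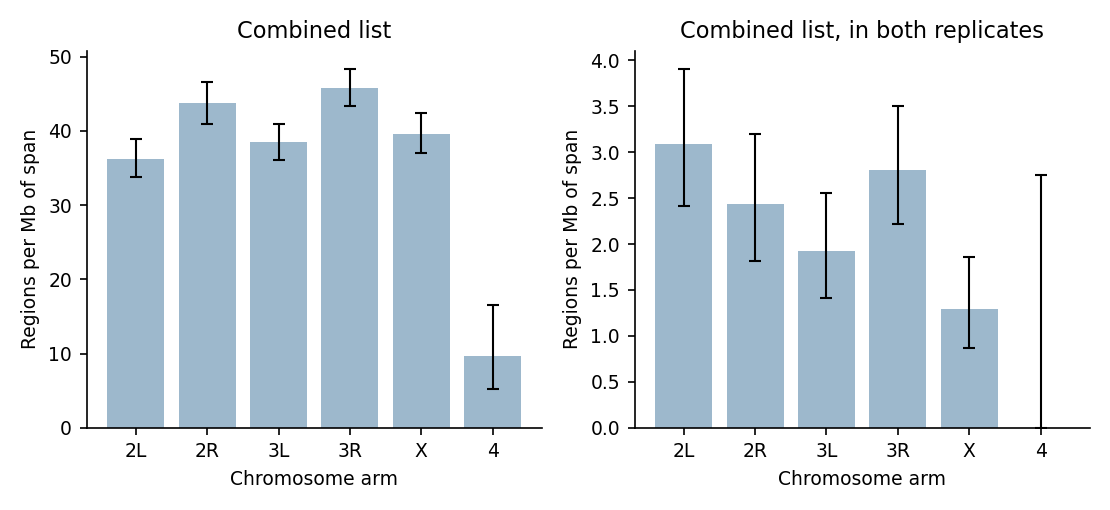
Regions per Mb of span (vertical axes, different scales) on each chromosome arm for the combined list (left) and for its regions overlapped by both replicates (right); bars are densities and lines are 95% exact Poisson intervals. X stands at 39.6 on the left, within the range of the other large arms, and at 1.30 on the right, the lowest of the large arms; chromosome 4 has no region on the right.

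Neighbouring regions lay closer together than randomly placed ones in each replicate, while the combined list did not pass the same test. The median distance from a region's centre to the nearest other centre was 56.5 kb in replicate 1 against 67.6 kb under random placement within chromosomes (2-sided permutation p = 0.0084). In replicate 2 it was 31.8 kb against 39.7 kb (2-sided permutation p = 0.0002, the smallest that 10000 placements can give). In the combined list it was 8.51 kb against 8.91 kb (2-sided permutation p = 0.0538), at the edge of the central 95% of placements, 8.51 to 9.32 kb. Placement without overlap between regions, added after the data were seen, gave 9.83 kb for the combined list (2-sided permutation p = 0.0002). The 2567 regions with the highest scores lay 15.8 kb apart against 17.9 kb (2-sided permutation p = 0.0012).

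**Figure D5:**
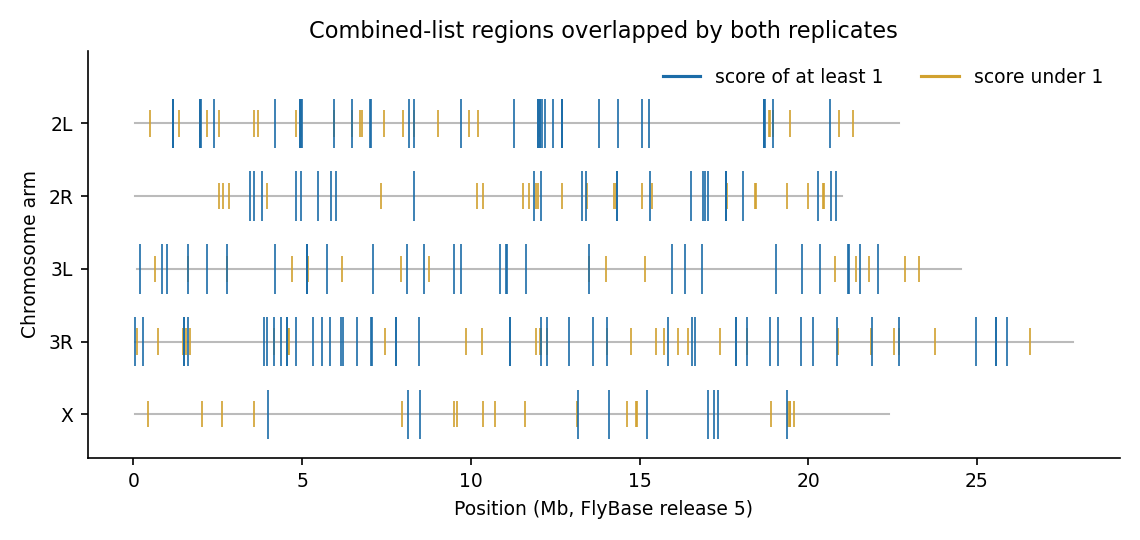
Position in Mb (horizontal axis) of the 275 combined-list regions overlapped by both replicates on the 5 large arms (vertical axis), with tall blue lines for a score of at least 1 and short yellow lines for a lower score; grey lines run from the first to the last combined-list region. X carries 10 blue lines and 2L carries 42.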

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

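Settings were fixed before the data were examined except those named here, or among the methods, as added after the data were seen. Of 64 alternative values over 12 results, 51 kept their direction and their side of the threshold, or stayed within the spread allowed for a value without a test. The shared regions of the replicates exceeded chance under every overlap rule, list length and placement scheme tried, with 33.9% of replicate 1 shared when centres had to lie within 250 bp and 58.0% among the 336 and 528 highest scores. The X share stayed under its share of length in all 6 settings tried, all added after the data were seen. They were limited to regions supported by both replicates, strong regions of a replicate, or the 200 strongest combined-list regions on the large arms. The planned limit to the 2567 highest combined-list scores was not among them. In that set X was the densest large arm, at 30.4 regions per Mb. The lists of 336, 528 and 2567 regions are shorter than the full lists by construction. Support of the combined list from either replicate was 21.7% among its 2567 highest scores, and ranged from 10.8% to 17.5% with a single replicate, which follows from leaving lists out. It was 42.0% among combined-list regions of at least 1301 bp, added after the data were seen, a limit that removes regions narrower than any replicate region. The difference in score percentile by support ranged from -1.90 to 24.7 with a single replicate and changed sign when replicate 1 was left out. Of the 901 regions overlapped by replicate 2, 626 were overlapped by it only, with a median percentile of 33.7, so they made up most of that group. Among regions of at least 1301 bp, those supported by exactly 1 replicate stood at 31.2, against 30.0 for neither (2-sided permutation p = 0.516). The gap to regions supported by neither was thus not found once narrow regions were left out. The 626 alone were not tested under that limit. Spacing, not past the threshold in the combined list, passed it in each replicate (31.8 to 56.5 kb) and among the 2567 highest scores (15.8 kb). It also did so, in settings added after the data were seen, for placement without overlap (8.51 kb against a longer chance distance) and for regions supported by both replicates (94.8 kb); the cause was not tested. No paired analysis was possible because the input libraries had no list of their own to compare with the ChIP lists of the same number. Alternatives for promoters, divergent promoters, gene lists and motifs were not run. Depth is unknown and limits what can be said of weak regions.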

Other observations

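All tests in this part were chosen after the data were seen. A minority of strong regions supported by both replicates lay close to another such region, more than in random draws. Among 157, 14 neighbouring pairs had centres within 10 kb, against 2.26 on average when as many regions were drawn from the combined list on each chromosome (1-sided permutation p = 0.0001, the smallest that 10000 draws can give). They formed 9 groups with 23 of the 157 regions. Groups of 2 regions spanned 6111 to 11687 bp in all, and the median width of the 157 was 3279 bp. Gaps between neighbours were not tested, and the draws do not model a wide enriched stretch divided into several regions. The draws therefore cannot decide whether a group holds separate sites or parts of the same stretch. A group on 2L from 18675460 to 18700148 held 4 regions with scores from 2.66 to 3.65, and another on 2L from 1162386 to 1178862 held 4 with scores from 1.19 to 3.65. A group on 3L from 5126904 to 5147070 held 3 with scores from 3.30 to 4.23, including the last of the 10 named regions.

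Weak regions differed between X and the large autosomal arms in score. The median score of weak regions was 0.44 on X against 0.37 on 2L, 2R, 3L and 3R in the combined list, 0.65 against 0.52 in replicate 1 and 0.58 against 0.50 in replicate 2 (2-sided permutation p = 1e-05 for each). On the large arms, weak regions of replicate 1 found in replicate 2 were wider than the others, with medians of 1817 and 1424 bp, and those of replicate 2 found in replicate 1 had medians of 1874 against 1465 bp (adjusted 2-sided permutation p = 2e-05 for each over 8 tests). Wider regions are also overlapped more often by chance, but with centres within 250 bp as the rule the medians were 1869 against 1425 bp and 1894 against 1471 bp (adjusted permutation p = 2e-05 for each). The shared weak regions of replicate 1 had lower scores than the others, 0.51 against 0.55 (adjusted permutation p = 0.0181 over the same 8 tests), and those of replicate 2 did not pass this test, at 0.53 against 0.51 (adjusted permutation p = 0.201).

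Strong regions supported by both replicates were sparse on X, at 6.37% against 16.1% for the weak ones (Fisher's exact p = 0.016). Without the limit to supported regions, the 200 strongest combined-list regions on the large arms had 10.5% on X. Fewer copies of X in male embryos could lower scores there. With the bar at a score of 2 on the autosomal arms and 1 on X, X held 7.19% of strong regions (interval 3.95 to 12.7) against 18.9% of length. That is the shift of a single copy against 2 if scores are on a log2 scale and every X is single-copy. The lists were called with input, which may carry the same copy number. Moving the bar also does not test whether regions on X are called less readily. The comparison therefore cannot decide whether copy number plays a part. Weak regions had 18.7% on X in the combined list, 20.2% in replicate 1 and 16.6% in replicate 2 (interval 14.3 to 19.3 in replicate 2). These shares lay above the interval of 3.50 to 11.3 for the strong regions supported by both. Most weak regions were not supported by both, so the sets are unlike. Among weak regions supported by both, the interval on X was 10.6 to 23.8, which overlaps that of the strong ones. For regions supported by both, the comparison thus cannot exclude fewer calls on X at every score. All weak regions had X densities 0.984, 1.08 and 0.857 times those of the autosomal arms in the combined list, replicate 1 and replicate 2. They thus showed no shortage on X like that of the strong regions. The full lists of replicate 1 and replicate 2 had ratios of 0.871 and 0.761. Both include the scarce strong regions, and replicate 1 did not pass its test (adjusted exact binomial p = 0.304). Some part of the shortage may still come from calling. Mappability and local depth were not tested, nor was a biological explanation.

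High scores also occurred without support, in 170 strong combined-list regions that neither replicate held. Their scores were tied with another region in 72.9% (interval 65.8 to 79.1), against 0 of 157 strong regions supported by both (Fisher's exact p = 1.5e-51), and their median width was 1050 bp against 3279 bp. Of the 170, 85.9% (interval 79.9 to 90.3) were narrower than 1301 bp, the narrowest replicate region, against 0 of 157 (Fisher's exact p = 6e-68). Overlap with replicate regions of at least 1301 bp favours this difference by construction, so the test cannot decide whether width explains the missing support. Among all 3952 combined-list regions that neither replicate held, strong and weak, 65.9% were narrower than 1301 bp. The different minimum width of the lists remains a candidate explanation. Another is that these scores rest on few reads, which leave few possible ratios, although ties are common in the combined list as a whole (2599 of 5135 scores) and do not mark these regions by themselves. Of the 170, 74.7% (interval 67.7 to 80.6) lay off the large arms, against 0 of 157 strong regions supported by both (Fisher's exact p = 1.4e-53). In the combined list as a whole, 94.2% of regions lay on the large arms. Sequence off the large arms does not account for all of the 170, since the other 43 lay on the large arms. Neither repeated sequence nor a biological explanation was tested.

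Weak regions were shared in 102 of 478 cases when both members had to be weak. Chance overlap of randomly placed regions would give 10.6, so the observed number was 9.63-fold higher (1-sided permutation p = 0.0001). Equal-chance draws of replicate 2's weak regions from the weak regions of the combined list would give 71.5, and the observed number was 1.43-fold higher (1-sided permutation p = 0.0001). Of all 5135 combined-list regions, 2814 were narrower than 1301 bp, a width that neither replicate list holds. Such regions in the pool may set the number from draws too low. The draws therefore cannot decide whether weak positions recur between replicates more often than chance choice among the wider regions would give. Whether the shared weak regions are weak binding or open chromatin recovered by any antibody was not tested.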
